A study of Escherichia coli with 10 samples.

How the data were processed

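RNA was sequenced from Escherichia coli cultures grown with or without the tetrapeptide DYDD (Asp-Tyr-Asp-Asp). Per the labels, the strain was ATCC 25922, a reference strain used in antibiotic susceptibility testing. Bacteria went into 200 mL of medium with either 200 µL of sterile water or the peptide as a solution of 50 mg/mL, and were collected after 24 h. The 50 mg/mL is that of the solution before it was diluted, with 200 µL of it going into 200 mL of medium. The concentration in the culture is not stated in the sources used here, but follows from these volumes. The library kit named in the labels starts from total RNA. The peptide and the groups are written in more than one way in the labels, with DDDY beside DYDD, so samples were assigned by their titles, which give 5 control and 5 DYDD libraries. The labels do not say that the 5 replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

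The authors deposited a single table of read counts per gene, with a column for each of the 10 samples, and 0 columns were left unused. The counts are raw, whole numbers. Of the 41290 values 0 are odd, so both reads of a pair were probably counted. The deposited counts were used as they stand. Per the submitters' processing notes, Bowtie 0.12.2 was used and the build named was mm8, a mouse build, with no role given for either. The counter, the filters and the treatment of strand are not given in the sources used here. Without strand, reads of overlapping or antisense genes cannot be told apart.

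The gene IDs are locus tags of E. coli K-12 BW25113, a different strain from the one in the labels. They were paired through their shared locus number with gene symbols of E. coli K-12 MG1655 (assembly ASM584v2). Of the 4129 IDs, 4128 had a symbol, of which 4124 are annotated as protein coding, 4 as pseudogenes and 0 as rRNA or tRNA. As a check of the pairing, all 8 genes deleted or disrupted in BW25113 were absent. No genome of the cultured strain or of BW25113 was used here, so no coordinates are given, and gene length and GC content were not examined. Differences in sequence between the cultured strain and the reference would lower the counts of diverged genes in both groups alike. With no rRNA features, the planned share of rRNA counts and the alternative without rRNA were not run.

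The fit of the main comparison, the gene lists, the rule for named genes and a first set of alternatives were chosen before the data were examined. Counts were filtered with filterByExpr, scaled by TMM factors and compared with the quasi-likelihood F-test of edgeR 4.0.16 (robust fit, R 4.3.3), with group as the only term and Benjamini-Hochberg adjustment over the 3703 genes that passed the filter. The filter removed 426 genes, of which 130 had counts. The threshold was an adjusted p under 0.05. CPM values are TMM-scaled. Errors of log2 fold changes are standard errors derived from the F statistic, and errors of CPM are SDs over 5 libraries. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run as alternatives. DESeq2 gave an adjusted p for 3684 genes and NA for 149, which were left as NA.

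A total of 44 gene lists with 1104 symbols was fixed from textbook knowledge of E. coli K-12, and 1056 of the symbols were found among the IDs, 8 of them through a synonym. The symbols papA, papC, papD and papG, 4 genes of a fimbria, were kept out because in K-12 these names are old synonyms of ATP synthase genes. The list of rRNA genes had no members, and the other 43 lists were tested with camera on log2 CPM (prior count 2) at a preset correlation of 0.01, for lists of at least 5 tested members. Camera asks whether the members of a list lie higher or lower than the other genes. Camera with an estimated correlation and fry were run beside it.

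The rule for named genes took, among genes with an adjusted p under 0.05, a mean of at least 10 CPM and no overlap between the groups, the 12 highest and the 12 lowest log2 fold changes, which gave 0 genes. For each list described, it took up to 4 members past the threshold or, where none passed, the 2 with the smallest p. Genes named outside this rule are said in the text to be chosen after their values were seen.

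The alternatives were other scalings, other tools, other low-count filters, the replicate number as a block, a minimum fold of 1.5, another prior count of 0.5 and leaving out each library in turn. Added after the data were seen were halved counts, the newer quasi-likelihood method of edgeR, limma-voom with quality weights, surrogate variables (sva 3.50.0, 2 variables), the lipopolysaccharide list without its lipid A modification genes, and fits without libraries that stood apart. Library totals and shares were compared with exact two-sided permutation tests over 252 assignments, whose smallest possible p is 0.00794.

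The pipeline was tested on simulated counts for this comparison, drawn for 3703 genes from the real means, library sizes and dispersions, with 200 genes changed. At an adjusted p under 0.05, edgeR recovered 12 of 50 genes changed 1.5-fold, 45 of 50 changed 2-fold, 47 of 50 changed 3-fold and 50 of 50 changed 4-fold. It made 160 calls, 6 of them on unchanged genes. DESeq2 made 189 calls, 26 of them on unchanged genes. With no change simulated, edgeR and DESeq2 each called 0 genes and camera 0 of 43 lists. A list of ribosomal protein genes shifted by 0.5 on the log2 scale was called by camera (adjusted p = 1.7e-17). The simulated libraries share no structure between genes, unlike the real ones.

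Depth was 15.6 to 93.2 M counts per library, and the common dispersion gave a coefficient of variation of 25.8% between libraries of a group. No pair of libraries within a group agreed within sampling noise. Over genes with at least 20 read pairs in the 2 libraries together, chi-square per degree of freedom lay between 24.8 and 372, so each library counted as 1 sample.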

Results

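Transcript levels were measured by RNA sequencing in Escherichia coli ATCC 25922, a reference strain for antibiotic susceptibility testing, to learn how the tetrapeptide DYDD acts against bacteria. The 10 libraries fall into 5 from control cultures and 5 from cultures given DYDD. Control replicates 1 to 5 held 22.6, 22.02, 25.6, 26.1 and 68.6 M counts. DYDD replicates 1 to 5 held 93.2, 25.6, 22.7, 17.1 and 15.6 M counts. The mean totals were 33.0 ± 19.99 and 34.8 ± 32.9 M counts (SD, n = 5 each; exact two-sided permutation p = 0.937). Between 3745 and 3819 of the 4129 genes had counts in each library. The 10 most abundant genes, among them oppA (oligopeptide uptake), ompA (an outer membrane protein) and gltA (citrate synthase), took 12.4 ± 1.03% of the counts in controls and 13.1 ± 1.01% with DYDD (SD, n = 5 each; exact two-sided permutation p = 0.302).

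The first principal component held 28.8% of the variance and the second 28.3%, and neither followed the groups alone. Control replicates 1 and 2 stood apart from the other controls on the first, at −16.8 and −21.8 against 3.90 to 9.31. Beside them on the first lay DYDD replicate 4, at −19.1, with the other DYDD libraries at −2.32 to 20.1. DYDD replicates 4 and 5 lay lowest on the second, at −29.3 and −18.0.

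**Figure D1:**
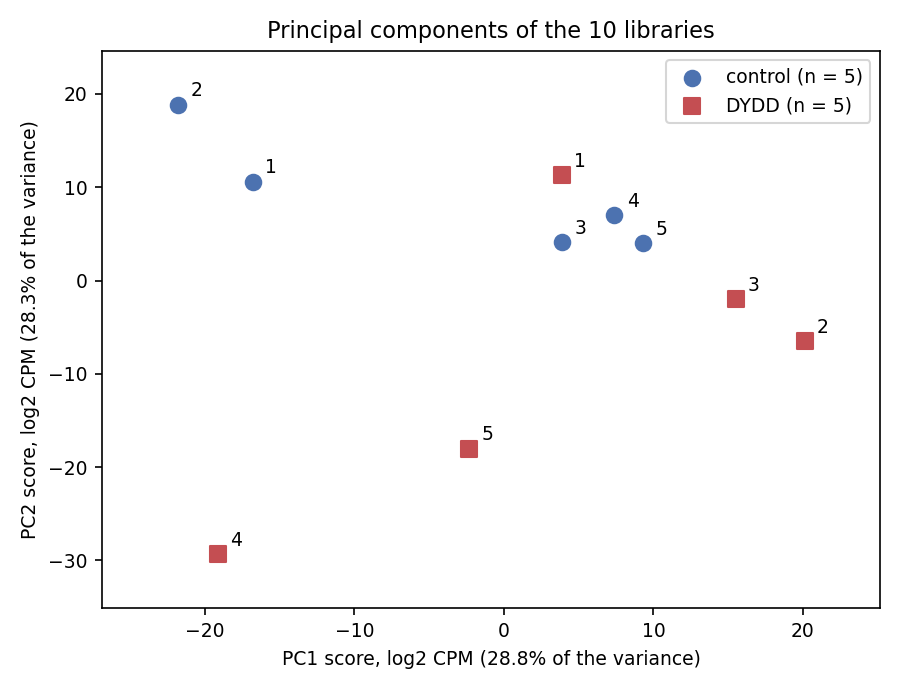
Scores of the 10 libraries on the first and second principal components of log2 CPM, with the replicate number beside each point (circles control, squares DYDD, n = 5 each). Control replicates 1 and 2 lie at −16.8 and −21.8 on the first component, with DYDD replicate 4 at −19.1, and DYDD replicates 4 and 5 at −29.3 and −18.0 on the second.

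The comparison of DYDD with control asks which genes differ in transcript level after 24 h with the peptide. The genes with the smallest p were named after their values were seen, since no gene met the rule for single genes. Several of them belong to the modification of lipid A, the membrane anchor of lipopolysaccharide. The level of ais (BW25113_2252), which lies beside the arn operon, was 18.5 ± 5.72 CPM in controls and 68.4 ± 31.9 CPM with DYDD (SD, n = 5 each), a log2 fold change of 1.88 ± 0.33 (SE). For arnA (BW25113_2255), which makes aminoarabinose for lipid A, the levels were 132 ± 27.7 and 393 ± 165 CPM (SD, n = 5 each; log2 fold change 1.58 ± 0.28, SE). The transferase gene arnT (BW25113_2257) had a log2 fold change of 1.36 ± 0.26 (SE), and eptA (BW25113_4114), which adds phosphoethanolamine to lipid A, 1.25 ± 0.24 (SE). The level of cysA (BW25113_2422), the ATPase of sulfate uptake, was 19.2 ± 6.49 CPM in controls and 56.3 ± 22.7 CPM with DYDD (SD, n = 5 each).

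Higher too was lsrF (BW25113_1517), of autoinducer breakdown, at 267 ± 15.4 CPM in controls and 393 ± 44.2 CPM with DYDD (SD, n = 5 each). On the lower side, gntR (BW25113_3438), the repressor of gluconate uptake genes, was at 381 ± 82.6 CPM in controls and 193 ± 32.3 CPM with DYDD (SD, n = 5 each; log2 fold change −0.98 ± 0.17, SE). The level of bhsA (BW25113_1112), an outer membrane protein linked to stress, was 29.4 ± 2.80 and 11.6 ± 4.43 CPM (SD, n = 5 each; log2 fold change −1.33 ± 0.24, SE). The log2 fold changes of ycfJ (BW25113_1110) and yqiJ (BW25113_3050) were −0.90 ± 0.16 and −1.11 ± 0.21 (SE), with yqiJ at −0.72 without control replicates 1 and 2. In each of these 10 genes all 5 DYDD values lay on 1 side of all 5 control values.

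**Figure D2:**
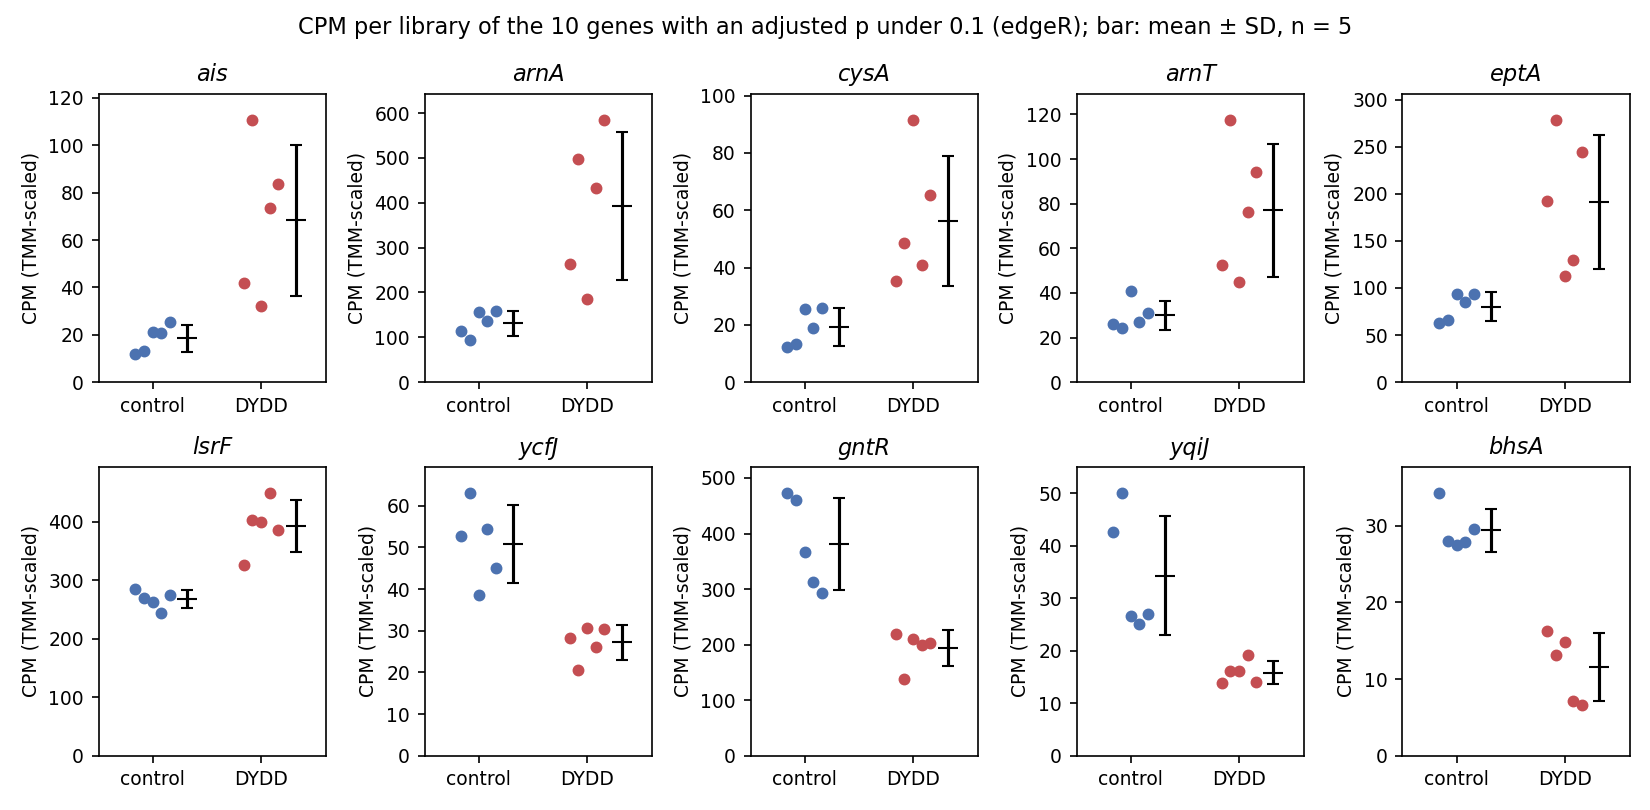
CPM (TMM-scaled) per library of the 10 genes with an adjusted p under 0.1 in edgeR, chosen after their values were seen (points: 5 control and 5 DYDD libraries; black bar: mean ± SD). The groups do not overlap in any of the 10 genes, of which 6 were higher and 4 lower with DYDD.

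No gene passed an adjusted p of 0.05 in edgeR: 0 of 3703 genes were called, and the smallest adjusted p was 0.0862, shared by 9 of the 10 genes above (lsrF 0.0924). At an unadjusted p under 0.05 there were 534 genes, 292 higher and 242 lower, where chance alone gives about 185. Other splits of the libraries into 5 and 5 gave a median of 113 and up to 830. As many as 534 came from 5 of 100 splits, the real one included, so chance is not excluded. The groups did not overlap in 163 genes, and chance gives on average 0.794% of the genes, or 29.4. Genes without overlap were not counted in the other splits. Since genes vary together, the difference from 29.4 was not tested against the structure of the samples. DESeq2 called 145 genes, 87 higher and 58 lower, the 10 genes above included, and limma-voom called 0. Without DYDD replicate 1 edgeR called 50 genes (30 higher, 20 lower), among them ais with an adjusted p of 0.0391, and without DYDD replicate 3 it called 6.

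Of the 43 gene lists tested, 18 were higher and 1 was lower as a set with DYDD by camera (adjusted p under 0.05). Camera with an estimated correlation called 0 of them (smallest adjusted p = 0.0931), and fry called 8, all among the 19. The 8 were iron acquisition, respiratory chain, amino acid catabolism, peptide transporters and peptidases, fatty acid synthesis, lipopolysaccharide, RNA polymerase and protein secretion. In the tests of single genes 0 members of any list passed over all genes, so members are given below with their values. With library totals as the only scaling the median of all genes shifted by −0.18, and the means of the glycolysis, heat shock, secretion and translation factor lists fell below 0.

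**Figure D3:**
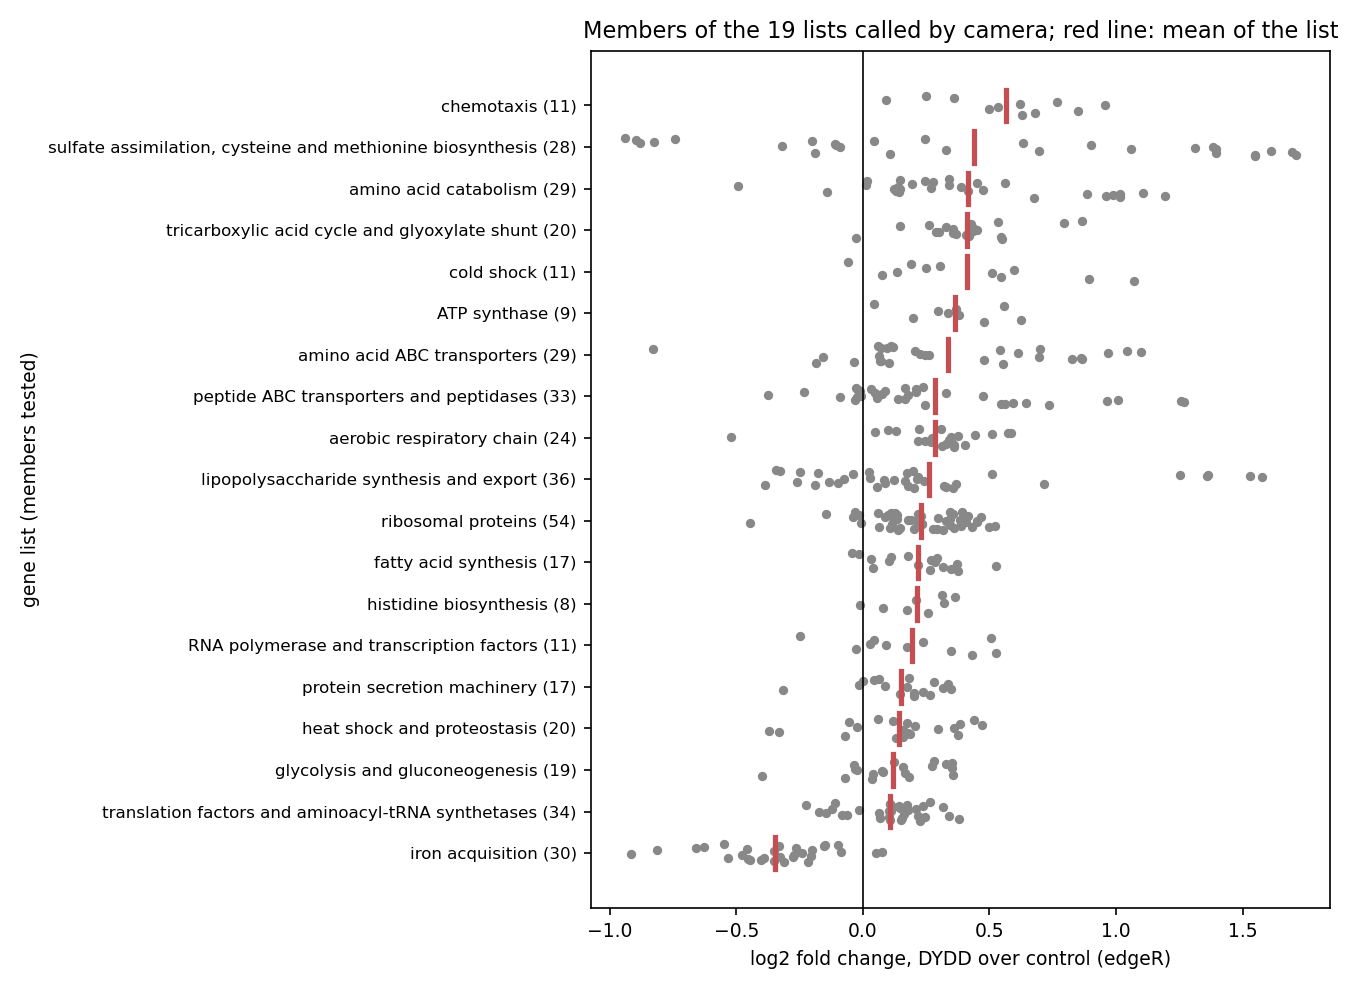
Log2 fold change (DYDD over control, edgeR) of each tested member of the 19 lists called by camera, with the mean of each list as a red line and the number of members in brackets. The means of 18 lists lie above 0 and that of the iron acquisition list lies at −0.35, but with library totals as the only scaling the means of glycolysis, heat shock, secretion and translation factors fall below 0.

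Genes of central metabolism and respiration were higher as sets. In the tricarboxylic acid cycle and glyoxylate shunt list 19 of 20 members had a log2 fold change above 0, with a mean of 0.41 (camera adjusted p = 9.7e-09; adjusted p = 0.259 with an estimated correlation). The aconitase gene acnB was at 6332 ± 1277 CPM in controls and 9239 ± 1426 CPM with DYDD (SD, n = 5 each), and aceK, the isocitrate dehydrogenase kinase, had a log2 fold change of 0.87 ± 0.28 (SE). Adjusted over the list alone 8 members were higher and 0 lower, beside 0 over all genes. The mean log2 CPM of this list was 10.9 in control replicates 1 and 2 and 11.5 to 11.6 in the other controls, and without these 2 libraries the mean log2 fold change was 0.23 and that of aceK 0.49. In the aerobic respiratory chain list 23 of 24 members were above 0, with a mean of 0.29 (camera adjusted p = 6.2e-06; adjusted p = 0.241 with an estimated correlation). Its members with the smallest p were nuoE of the NADH dehydrogenase (0.40 ± 0.12, SE) and cyoD of a terminal oxidase (0.57 ± 0.17, SE). No member passed over all genes, and 0 passed adjusted over the list alone. Without DYDD replicates 4 and 5 the mean of the respiratory list was 0.15.

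All 9 ATP synthase genes had values above 0, with a mean of 0.36 (camera adjusted p = 0.00116; adjusted p = 0.265 with an estimated correlation). The values of atpB and atpH were 0.62 ± 0.17 and 0.56 ± 0.16 (SE), and 2 members were higher adjusted over the list alone, beside 0 over all genes. In amino acid catabolism 27 of 29 members were above 0, with a mean of 0.41 (camera adjusted p = 1.9e-05; adjusted p = 0.0931 with an estimated correlation). The tryptophan permease gene tnaB was at 174 ± 47.9 and 352 ± 131 CPM, and astE of arginine breakdown at 201 ± 96.9 and 434 ± 94.6 CPM, in control and DYDD (SD, n = 5 each). In control replicates 1 and 2 astE was at 106 and 99.4 CPM against 211 to 307 in the other controls, and without them its log2 fold change was 0.71 in place of 1.11. Of the members 0 passed adjusted over the list alone, as over all genes.

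The list of glycolysis and gluconeogenesis had 14 of 19 members above 0 and a mean of 0.12 (camera adjusted p = 0.0422; adjusted p = 0.407 with an estimated correlation). The 2 members with the smallest p went opposite ways: pfkB, a minor phosphofructokinase, −0.40 ± 0.12 and fbaA, the main aldolase, 0.36 ± 0.12 (SE). The call was lost in 13 of 23 settings, with adjusted p up to 0.399 (without DYDD replicates 4 and 5), among them without control replicate 3 (adjusted p = 0.101), 4 (0.0832) or 5 (0.05003) and without DYDD replicate 1 (0.10), 4 (0.150; mean 0.07) or 5 (0.0630). With library totals only the mean was −0.07. Of its members 0 passed adjusted over the list alone, as over all genes.

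Iron acquisition was the list called lower. Of its 30 tested members 28 had values below 0, with a mean of −0.35 (camera adjusted p = 7.1e-07; adjusted p = 0.208 with an estimated correlation). The level of tonB, which powers outer membrane iron uptake, was 116 ± 13.8 CPM in controls and 84.3 ± 7.01 CPM with DYDD, and that of fes, which releases iron from enterobactin, 49.0 ± 18.9 and 25.9 ± 6.53 CPM (SD, n = 5 each). Both were lower adjusted over the list alone, beside 0 members over all genes, and both were DESeq2 calls.

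The lists of amino acid ABC transporters and of peptide transporters and peptidases were higher as sets. Among the amino acid ABC transporters 25 of 29 members were above 0, with a mean of 0.34 and a median of 0.22 (camera adjusted p = 0.000103; adjusted p = 0.241 with an estimated correlation). The ATPase genes hisP, of histidine uptake, and glnQ, of glutamine uptake, had log2 fold changes of 0.86 ± 0.20 and 0.70 ± 0.17 (SE). In the list 6 members were higher and 1 lower adjusted over the list alone, beside 0 over all genes. Of the 33 peptide transporter and peptidase genes 24 were above 0, with a mean of 0.29 and a median of 0.17 (camera adjusted p = 0.000203; adjusted p = 0.241 with an estimated correlation). The dipeptide uptake genes dppC and dppF had the smallest p, at 1.26 ± 0.29 and 1.01 ± 0.27 (SE). In this list 5 members were higher and 0 lower adjusted over the list alone, beside 0 over all genes. Chosen after their values were seen, dppB was at 1.27 ± 0.34 and the oligopeptide uptake genes oppB and oppF at 0.74 ± 0.20 and 0.65 ± 0.18 (SE). Without control replicates 1 and 2 the mean of the amino acid list was 0.22 and oppB was at 0.49. In those 2 libraries dppC was at 103 and 82.3 CPM, against 188 to 223 in the other controls. For dppF the values were 77.1 and 109 against 172 to 230 CPM, and for dppB 110 and 80.5 against 233 to 282 CPM.

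Genes for aspartate and tyrosine, the residues of the peptide, were not called as a set. Of the 23 members for their metabolism and uptake 18 were above 0, with a mean of 0.11 (camera adjusted p = 0.157; adjusted p = 0.639 with an estimated correlation). The aminotransferase gene aspC was at 0.33 ± 0.13 and aspA, the aspartate ammonia-lyase, at 0.28 ± 0.11 (SE). Without DYDD replicate 4 the mean was 0.0067, with library totals only it was −0.08, and without control replicates 1 and 2 the list was called higher (adjusted p = 0.0492; mean 0.17). Of these members 0 passed adjusted over the list alone, as over all genes.

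Sulfur genes divided within their list. Of the 28 members for sulfate assimilation, cysteine and methionine 17 were above 0 and 11 below, with a mean of 0.44 and a median of 0.29 (camera adjusted p = 0.0221; adjusted p = 0.279 with an estimated correlation). The members with the smallest p were cysA, of sulfate uptake, at 1.55 ± 0.30 and cysN, of sulfate activation, at 1.40 ± 0.30 (SE). Chosen after their values were seen, cysC, also of sulfate activation, was at 1.71 ± 0.43, and the sulfite reductase genes cysI and cysJ at 1.70 ± 0.38 and 1.61 ± 0.41 (SE). In control replicates 1 and 2 cysI was at 23.1 and 17.7 CPM, against 34.9 to 57.1 in the other controls. For cysJ the values were 31.3 and 29.0 against 55.8 to 88.4 CPM. With DYDD both were highest in replicate 3, at 221 and 330 CPM. Both were lowest in DYDD replicate 4, at 63.3 and 91.3 CPM, close to the highest control. Of 8 methionine biosynthesis genes, grouped after their values were seen, 6 were below 0 and 2 above (highest 0.24), with a median of −0.78 and 2 DESeq2 calls. Among them metF, metB, metA, metR and metK were at −0.90, −0.82, −0.88, −0.94 and −0.74, and without control replicates 1 and 2, which stood apart, at −0.56, −0.36, −0.27, −0.40 and −0.25. In all, 10 members were higher and 6 lower adjusted over the list alone, beside 0 over all genes, and DESeq2 called 9 higher and 2 lower. Without DYDD replicate 1 the list missed the threshold, at an adjusted p of 0.0571 with a mean of 0.48.

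In lipopolysaccharide synthesis and export 25 of 36 members were above 0, with a mean of 0.26 and a median of 0.17 (camera adjusted p = 0.00276; adjusted p = 0.0931 with an estimated correlation). The members with the smallest p were arnA and arnT, at 1.58 ± 0.28 and 1.36 ± 0.26 (SE). Adjusted over the list alone 8 were higher and 1 lower, beside 0 over all genes. The call rested on 5 members, arnA, arnB, arnC, arnT and eptA: without them the other 31 had a mean of 0.07 and the list was not called (adjusted p = 0.168; 20 above 0, 11 below). The rest of the arn operon, chosen after its values were seen, had arnC at 1.53, arnD at 1.42, arnB at 1.36, arnE at 1.15 and arnF at 0.75. Two-component signalling was not called (32 members; camera adjusted p = 0.149; mean −0.08), but its members with the smallest p were basS, the sensor that controls the arn genes, at 0.70 ± 0.18, and its regulator gene basR at 0.54 ± 0.17 (SE). Of the signalling list 0 members passed adjusted over the list alone, as over all genes.

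Lists of the transcription and translation machinery were higher as sets. Of 54 ribosomal protein genes 48 were above 0, with a mean of 0.23 (camera adjusted p = 1.9e-05; adjusted p = 0.313 with an estimated correlation). The values of rpsM and rpsK were 0.52 ± 0.14 and 0.50 ± 0.14 (SE), and 0 members passed adjusted over the list alone, as over all genes. Without DYDD replicate 4 the mean of the ribosomal list was 0.14. RNA polymerase and transcription factors had 9 of 11 members above 0 and a mean of 0.19 (camera adjusted p = 0.0215; adjusted p = 0.241 with an estimated correlation). The core subunit genes rpoB and rpoA were at 0.53 ± 0.14 and 0.43 ± 0.17 (SE), with 1 member higher adjusted over the list alone and 0 over all genes. This call was lost in 4 of 23 settings: without DYDD replicate 1 (adjusted p = 0.10), control replicate 5 (0.05003) or DYDD replicates 4 and 5 (0.0748), and with library totals only (0.0642), where the mean was 0.0060. Without DYDD replicate 4 alone rpoA was at 0.27. Translation factors and aminoacyl-tRNA synthetases had 26 of 34 members above 0 and a mean of 0.11 (camera adjusted p = 0.0166; adjusted p = 0.541 with an estimated correlation), with frr, of ribosome recycling, at 0.34 ± 0.13 and fusA, an elongation factor, at 0.38 ± 0.16 (SE). Of its members 0 passed, over all genes or adjusted over the list alone. That call was lost in 5 of 23 settings, among them without DYDD replicate 1 (0.162) or DYDD replicate 4 (0.0575; fusA 0.21), with adjusted p up to 0.284 with library totals only, where the mean was −0.08.

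Fatty acid synthesis had 15 of 17 members above 0 and a mean of 0.22 (camera adjusted p = 0.0012; adjusted p = 0.241 with an estimated correlation), with fabB, of chain elongation, at 0.53 ± 0.16 and accC, of the carboxylase, at 0.35 ± 0.12 (SE). Cold shock had 10 of 11 members above 0 and a mean of 0.41 (camera adjusted p = 0.00276; adjusted p = 0.241 with an estimated correlation), with the RNA-binding genes cspB at 0.89 ± 0.26 and cspC at 0.55 ± 0.16 (SE). Adjusted over the list alone 2 cold shock genes were higher and 0 fatty acid synthesis genes passed, beside 0 over all genes in both. Without control replicates 1 and 2 the cold shock call was lost (adjusted p = 0.0575). Histidine biosynthesis had 7 of 8 members above 0 and a mean of 0.21 (camera adjusted p = 0.0149; adjusted p = 0.313 with an estimated correlation), with the biosynthetic genes hisH at 0.37 ± 0.12 and hisF at 0.32 ± 0.14 (SE). No member passed over all genes and 0 passed adjusted over the list alone, and the call was lost in 5 of 23 settings, with adjusted p up to 0.25 (without control replicates 1 and 2; mean 0.10), among them without DYDD replicate 1 (0.0913) or control replicate 1 (0.10). With library totals only the mean of the histidine list was 0.04.

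All 11 chemotaxis genes were above 0, with a mean of 0.57 (camera adjusted p = 0.00628; adjusted p = 0.562 with an estimated correlation). The phosphatase gene cheZ was at 28.0 ± 3.88 CPM in controls and 54.5 ± 29.3 CPM with DYDD, and the receptor gene tap at 54.3 ± 12.2 and 92.5 ± 50.7 CPM (SD, n = 5 each). The mean log2 CPM of the list was 6.41 and 6.0 in DYDD replicates 2 and 4 and 4.92 to 5.14 in the other DYDD libraries, against 4.84 to 5.39 in controls. The call was lost in 5 of 23 settings, with adjusted p up to 0.316 (with surrogate variables): among them without DYDD replicate 2 (adjusted p = 0.106; mean 0.29, tap 0.42) and without DYDD replicate 4 (0.0541). Flagella and motility were not called (39 members; camera adjusted p = 0.376; mean −0.01), with flgB at −0.59 ± 0.26 and fliI at −0.64 ± 0.30 (SE), but were lower as a set without control replicate 4 (adjusted p = 0.0309) or DYDD replicate 2 (0.0428). With all libraries and an estimated correlation the camera adjusted p of the flagella list was 0.843. Without control replicate 5 flgB was at −0.34. In both lists 0 members passed adjusted over the list alone, as over all genes.

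Heat shock and proteostasis had 15 of 20 members above 0 and a mean of 0.14 (camera adjusted p = 0.0144; adjusted p = 0.407 with an estimated correlation), with the protease genes ftsH at 0.44 ± 0.12 and lon at 0.36 ± 0.11 (SE). It was lost in 3 of 23 settings, without DYDD replicate 2 (0.0670) and with adjusted p up to 0.194 with surrogate variables, and with library totals only the mean was −0.03. Protein secretion machinery had 14 of 17 members above 0 and a mean of 0.15 (camera adjusted p = 0.0221; adjusted p = 0.241 with an estimated correlation), with the signal peptidase gene lepB at 0.34 ± 0.11 and yajC, of the translocase, at 0.32 ± 0.11 (SE). It was lost in 4 of 23 settings, without control replicate 1 (0.0624) and with adjusted p up to 0.154 with library totals only, where the mean was −0.03. In the heat shock and secretion lists 0 members passed adjusted over the list alone, as over all genes.

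Several stress lists were not called. Envelope stress had a mean of −0.04 but a median of 0.12, and camera pointed upward (31 members; adjusted p = 0.406). Adjusted over the list alone 2 of its members were higher and 3 lower, beside 0 over all genes, with rseB, of the sigma E pathway, at 0.41 ± 0.11 and the phage shock gene pspB at −0.92 ± 0.22 (SE). Phosphate starvation (22 members; adjusted p = 0.265; mean 0.13, or −0.04 with library totals only) had 3 members higher adjusted over the list alone and 0 over all genes, with the glycerol phosphate uptake genes ugpC at 0.60 ± 0.14 and ugpE at 0.82 ± 0.20 (SE). Oxidative stress defence (30 members; adjusted p = 0.454; mean −0.06) had sodC, a superoxide dismutase, at −0.31 ± 0.13 (SE) and hemH, of heme synthesis, at −0.22 ± 0.13 (SE; −0.14 without control replicate 2). Multidrug efflux (25 members; adjusted p = 0.368; mean −0.07) had mdtF, an efflux pump, at 0.48 ± 0.18 (SE) and the activator marA at −0.41 ± 0.21 (SE; −0.18 without control replicates 1 and 2). SOS and DNA repair (21 members; adjusted p = 0.34; mean −0.12) had umuC, of lesion bypass, at −0.30 ± 0.12 (SE) and ruvB, of recombination, at 0.26 ± 0.12 (SE). In the oxidative stress, efflux and SOS lists 0 members passed adjusted over the list alone, as over all genes. The SOS list was lower as a set without control replicate 2 (adjusted p = 0.0311, mean −0.20) and without control replicates 1 and 2 (adjusted p = 0.000199). Its mean log2 CPM was 6.33 and 6.23 in those 2 libraries and 6.68 to 6.96 in the other controls. With all libraries and an estimated correlation its camera adjusted p was 0.769.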

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

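Of 246 groups of 5 library values tested, 9 held a library set apart from the other 4, where chance at 1 in 20 gives about 12.3. Most of these values are CPM of genes chosen by small p and not independent, so 12.3 is only a rough guide. It does not explain the library totals below. A library was set apart when its gap to the nearest other, divided by the range of the group, exceeded the critical value of 0.71. The test of single values was planned, and no explanation of these values was tested.

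Control replicate 5 had a total of 68.6 M counts, against 22.02 to 26.1 M in the other controls, with a gap of 0.9118 of the range. DYDD replicate 1 had 93.2 M, against 15.6 to 25.6 M (0.8716). Among the genes named, fes (iron release) was at 82.4 CPM in control replicate 2 and 37.5 to 45.2 in the other controls (0.8298). The level of accC (fatty acid synthesis) was 644 CPM in control replicate 3 and 538 to 556 in the others (0.8269). In control replicate 4 fusA (an elongation factor) was at 3251 CPM, against 3598 to 3713 (0.7511). With DYDD, cysW (sulfate uptake) was at 112 CPM in replicate 3 and 39.8 to 60.0 in the others (0.7183). The value of gntR (the gluconate repressor) was 137 CPM in DYDD replicate 2 and 199 to 218 in the others (0.7582). In DYDD replicate 1 lsrD (autoinducer uptake) was at 116 CPM against 227 to 267 (0.7358), and yjcH (of the acs operon) at 387 CPM against 737 to 829 (0.7923).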

How the results depend on the processing

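The alternatives chosen after the data were seen were halved counts, the newer edgeR dispersion, quality weights, surrogate variables, the lipopolysaccharide list without 5 genes and the fits without 2 or 3 libraries; the others were planned. The count of 0 genes in edgeR was 0 under the other scalings, limma-voom, both other filters, the minimum fold, halved counts, the newer dispersion and the fits without 2 or 3 libraries. DESeq2 called 145 genes, limma-voom with quality weights 86 (71 shared with DESeq2) and surrogate variables 40 (29 shared). Leaving out 1 library gave 0 to 50 genes: 50 without DYDD replicate 1, 6 without DYDD replicate 3 and 0 without each other library. With the replicate block 0 genes and 18 lists were called; by same-number correlations of −0.39 to 0.10 the numbers did not pair the libraries. All 92 named genes kept their sign in each of the 25 alternatives that gave them a value, but not their size. They were chosen by small p or by their values in these same libraries. A change of sign was therefore unlikely from the start, and the kept signs are not separate support. The filter of a mean CPM of at least 10 gave a value for 87 of them. The log2 fold change was smaller by over 1.5 times in 32 with surrogate variables (tnaB 0.51 from 1.01, cspB 0.46 from 0.89, cyoD 0.25 from 0.57). It was smaller by as much in 23 with library totals only (larger in 3), in 17 without control replicates 1 and 2, and in 21 without these and DYDD replicate 4. The same held for 9 without DYDD replicates 4 and 5, for 9 with quality weights and for at most 2 with 1 library left out. With surrogate variables the mean of the tricarboxylic acid cycle list was 0.26, from 0.41. Of 19 lists, 0 were called with an estimated correlation, 8 by fry, and 14 (without DYDD replicate 1) to 21 (without control replicate 2) with 1 library left out. The cause of these differences was not tested. In 10 lists the call held in 23 of 23 settings of camera with the preset correlation: tricarboxylic acid cycle, iron, respiration, amino acid catabolism, ribosomal proteins, both transporter lists, ATP synthase, fatty acid synthesis and lipopolysaccharide, whose call was lost without its 5 lipid A modification genes (adjusted p = 0.168). Of these 10, fry did not call tricarboxylic acid cycle (fry adjusted p = 0.0612), ribosomal proteins (0.123), ATP synthase (0.0682) or amino acid ABC transporters (0.0638). The 23 settings all preset a correlation of 0.01, where that estimated for the tricarboxylic acid cycle list was 0.53. They therefore do not test the choice of correlation. Totals differed by 1.84 M counts, and by 1.22 M without the 10 most abundant genes (exact permutation p = 0.944). With no rRNA features the alternative without rRNA was not run. In simulated data 12 of 50 genes changed 1.5-fold were recovered, so changes of that size were mostly not detectable there. The simulated libraries share no structure between genes, so recovery in the real libraries may be lower, also for larger changes.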

Other observations

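Tests chosen only after the result was seen were those of the scaling for the lipid A genes, of the libraries that stand apart for the iron list and of neighbouring genes at 0; the groups in the next paragraph were also chosen after their values were seen.

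Several other operons and regulons had all or most of their genes on 1 side of 0, and the genes repressed by GntR did not. All 8 genes of the lsr operon, which takes up and breaks down an autoinducer, were above 0, with a median log2 fold change of 0.57 and 4 DESeq2 calls. Among them lsrC was at 1.06 ± 0.31 and lsrB at 0.56 ± 0.13 (SE, n = 5 each). All 13 phenylacetate degradation genes were above 0 (median 0.70, 4 DESeq2 calls), with paaI at 1.19 ± 0.31 and paaH at 1.19 ± 0.36 (SE, n = 5 each). The 3 genes of the acs operon, of acetate uptake and use, were at 1.36 ± 0.39 for yjcH, 1.22 ± 0.32 for actP and 0.69 ± 0.41 for acs (SE, n = 5 each). Control replicates 1 and 2 had 1712 and 1641 CPM of acs, against 6223 to 7742 in the other controls, and without them the values were 0.89 for yjcH, 0.82 for actP and 0.18 for acs. In the lsr operon lsrC was at 0.70 without the same 2 libraries. In these 2 libraries paaH was at 33.4 and 28.8 CPM, against 49.9 to 75.8 in the other controls. For paaI the values were 18.0 and 8.31 against 15.7 to 24.2 CPM. The histidine transport gene hisP was at 48.5 and 56.4 against 76.4 to 98.6 CPM. All 9 genes of the histidine and glutamate transport operons were above 0 (median 0.86, 5 DESeq2 calls), as were all 18 sulfate genes of the cysteine regulon (median 1.35, 11 DESeq2 calls), with tsuA, of thiosulfate uptake, at 1.48 ± 0.38 (SE, n = 5 each). In control replicates 1 and 2 tsuA was at 14.5 and 7.02 CPM, against 19.2 to 24.8 in the other controls. Of the 7 phage shock genes 6 were below 0 (median −0.89, 3 DESeq2 calls), with pspG at −1.34 ± 0.38 and pspD at −0.91 ± 0.27 (SE, n = 5 each). The 5 genes repressed by GntR, whose own gene had a value of −0.98, had a median of −0.13, with 2 above 0 and 3 below. None of these genes passed in edgeR at an adjusted p of 0.05, where 0 genes were called, 534 had an unadjusted p under 0.05, DESeq2 called 145 and limma-voom 0.

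Whether chance assignment of the libraries could give such counts was tested with 100 of the 126 splits into 5 and 5, the real split included. The edgeR calls cannot be tested this way, because with a real count of 0 all 100 of 100 splits are as large by construction (highest other 48). For genes with an unadjusted p under 0.05 (real 534, highest other 830; 5 of 100) chance cannot be excluded. For DESeq2 calls (real 145, highest other 340) 3 of 100 splits gave as many, the real one included. For the number of lists called by camera (real 19, highest other 19) it was also 3 of 100. Both shares are under 0.05, but other splits matched or passed the real counts, and not all 126 splits were run, so chance is not excluded. The other splits with 19 lists exchanged only a single control and a single DYDD library. They kept most of the real contrast, so they say little about chance. The other splits called a median of 7 lists, so the test of the number does not hold for each of the 19 lists. The split of control replicates 1 and 2 and DYDD replicates 1, 4 and 5 from the rest gave 340 DESeq2 calls and 48 in edgeR, and that of control replicates 1, 2 and 3 and DYDD replicates 4 and 5 gave 182 in DESeq2, which points to a structure of the samples other than their group. The labels name no batch, so no value within a batch can be had.

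The 9 genes ais, arnA to arnF and arnT, and eptA were all above 0 with DYDD, with a median log2 fold change of 1.36. With library totals only, the median of all genes shifted by −0.18 and that of the 9 genes was 1.19, the lowest over 4 scalings. The scalings compared thus differed too little to account for the whole of 1.36. With each library left out in turn the lowest median was 1.16. Without control replicates 1 and 2 and DYDD replicate 4 it was 1.26. The 9 genes were grouped because several had a small p in these same libraries. Leaving libraries out could therefore hardly bring their median near 0, and these values are not separate support. A response of the wider PhoP regulon is argued against, as 9 other PhoP targets were all below 0 (median −0.26), among them slyB at −0.39 ± 0.16 and rstA at −0.70 ± 0.26 (SE, n = 5 each; −0.24 and −0.46 without control replicates 1 and 2, and slyB −0.26 without control replicate 1 alone). A candidate explanation left open is signalling through BasS and BasR, whose genes lay at 0.70 and 0.54 (1 operon, chosen after its values were seen). Their locus numbers run on to that of eptA (BW25113_4112 to BW25113_4114), 1 of the 9 genes, so these values are not separate support. The explanation was not tested otherwise. This is a hypothesis, found and examined in the same data, and no gene of the 9 passed the adjusted threshold in edgeR with all libraries.

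The iron acquisition list was lower and the citric acid cycle and respiratory lists were higher, as a larger iron supply with stronger Fur repression and weaker RyhB repression might give. None of the 3 lists was called by camera with an estimated correlation (adjusted p = 0.208, 0.259 and 0.241). Genes repressed by Fur outside the iron list had a median of −0.085 (7 above 0, 9 below) and genes repressed by RyhB outside the citric acid cycle and respiratory lists a median of 0.020 (7 above, 6 below), with iscS at 0.64 ± 0.25 (SE, n = 5 each; 0.31 without control replicates 1 and 2). With members on both sides of 0, these medians decide nothing, and this explanation cannot be told apart from others. The libraries that stand apart are argued against for the iron list, whose mean was −0.33 without control replicates 1 and 2 and DYDD replicate 4. For the citric acid cycle the mean fell to 0.20 without those 3 libraries, from 0.41.

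Of the 4129 gene IDs 296 had no count in any of the 10 libraries. Genes of the K-12 reference that the cultured strain lacks are a candidate explanation: among the 4002 genes that could be put in order, 281 of them at 0, 216 neighbouring pairs were at 0, where 10000 shuffles of the order gave at most 36. Runs of at least 5 genes at 0 numbered 16 and held 204 of the 281, among them ykfI to intF (31), intA to ypjF (21) and cas2 to cas3 (8). Low expression at this depth cannot be told apart for the remaining genes at 0, since 105 genes had totals of 2 to 100 counts, between the bounds set for either outcome. Without a genome of the strain, absence of a gene was not examined directly.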
